A study of Mus musculus with 40 samples.

How the data were processed

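RNA sequencing had been done on polyadenylated RNA of mouse liver (tissue liver and cell type hepatocytes per the labels) from 40 samples in 9 groups, set by age (3 or 12 months), hours after PH (0, 48 or 72) and ATRi treatment given at 24 h. Neither the dose unit of ATRi nor the extraction protocol is given in the sources used here. The authors deposited 12 tables of expression levels in the unit log2 of a value they call sigma, which the sources do not define. The submitters' processing notes name the genome build GRCm38/mm10. The aligner, the counting, the scaling between samples and any filter are not given. The tables give no read counts, so the depth of each sample is unknown, and no interval that needs it is given.

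Each table lists the same 11119 genes with a position in bins of 10000 bp. For 8 groups the tables hold 1 mean over 3 to 8 mice, made by the authors in a way not stated. For the 12-month ATRi group at 72 h they hold the mean and the levels of its 4 livers, named by mouse (M545, M546, M547 and M548). The deposited mean of this group is not the mean of the 4 livers' log2 levels, with a median offset of 0.088 (−0.115 at mean levels above 0 and up to 1, and 0.225 above 4 and up to 5). Of the genes, 10409 (93.6%) were matched by symbol and chromosome to 1 gene of GENCODE mouse release M21, which gave identifiers, coordinates and intron lengths. Some 507 entries join overlapping genes under 1 name, and 20 pairs of close neighbours ran in parallel across the tables, so members of such pairs may share reads.

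Comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Values were left on the authors' scale with no further normalization. A filter to the 12000 genes with the highest mean had been fixed and removed nothing. The difference of each comparison is the first group's log2 level minus the second's. In 11 comparisons both groups have only means, and genes were counted at a difference of 1 or more in either direction, without a test. Groups of genes were described through 33 fixed lists, 30 of which had 5 or more measured members: DNA replication and nucleotide supply, G1/S regulators, mitosis, ATR with checkpoint and fork repair, p53 targets, replication-dependent histones, interferon response, acute phase, inflammation and chemokines, immediate early genes, integrated and ER stress response, ribosome biogenesis, senescence-associated genes, bile acid, cholesterol and fatty acid synthesis, fatty acid oxidation and PPARα targets, pericentral, periportal and secreted hepatocyte genes, circadian clock outputs, male- and female-biased genes, sex chromosome genes, mitochondrially encoded genes and markers of 8 other cell types. The median of each list was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean level. The percentile describes the means compared and is not a p-value. Genes of a list can move together between mice, which random lists do not hold. A list can therefore stand apart through variation between mice alone.

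The other 5 comparisons involve the 4 single livers and were tested with limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg adjusted p under 0.05). Single livers entered with weight 1 and each mean as 1 observation weighted by its number of mice, with an intensity trend and robust empirical Bayes. The spread within a group therefore comes from the 4 ATRi livers alone, and the other groups are assumed to vary like them. The livers are also set against means made in a way not stated. An offset like that of the deposited mean could therefore be part of every tested difference. Lists were tested with cameraPR of limma, with a preset correlation of 0.01 and again with the correlation between genes estimated from the 4 livers, adjusted over the 30 lists. Estimates below 0 were set to 0, which is less strict than the preset value. This was so for G1/S regulators, fatty acid synthesis and stellate cell markers, among others. The p-values of cameraPR come from genes' moderated statistics. Because the 72 h mice of the labels also contribute to the 0 h means, the comparison of ATRi at 72 h with 0 h treats shared mice as independent. So does the borrowed spread for untreated mice at 72 h against 0 h at both ages.

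On simulated data made from the 4 livers' spread (5 runs with 200 changed genes each), the test recovered 33% of changes of 1 and 83.4% of changes of 2 on the log2 scale, 3.3% of calls were false, and data without change gave 0 calls. The simulation drew genes independently, with the livers' spread in both groups and no offset between livers and means. Its rates hold where these assumptions do and cannot be carried over to the real calls. Named genes are the 10 with the largest and the 10 with the smallest difference of each comparison (among genes past the test where there is one), passing over predicted and clone-named genes, up to 4 members of each list with the largest absolute difference, and Atr, Chek1, Cdkn1a, Mki67, Top2a, Ccnd1, Pcna, Mcm5, Rrm2, Alb and Cyp7a1. Outliers among the 4 livers were sought with Dixon's ratio. Alternatives were the 9000 genes with the highest mean, no filter, quantile normalization, centring on the median difference, the deposited mean in place of the 4 livers, a weight of 1 for each mean, limma without trend and robust fit, leaving out each liver, and a spread borrowed from the 4 livers for the 11 comparisons without a test. Removal of a lowess trend on intron length (span 0.3) and the deposited mean as the level in limma were chosen after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Other splits of the samples could not be counted, since no comparison has single values in both groups.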

Results

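RNA sequencing of polyadenylated transcripts gave expression levels in mouse liver, labelled as hepatocytes, before partial hepatectomy (PH, 0 h) and 48 and 72 h after it. PH removes part of the liver, and hepatocytes of the remnant then leave quiescence and divide. The mice were 3 or 12 months old, and some received ATRi 24 h after PH, an inhibitor of ATR, the kinase that signals stalled replication forks. The 40 samples fall into 9 groups. Before PH there were 7 mice at 3 months and 8 at 12 months. At 48 h there were 3 untreated mice at each age and 3 ATRi mice at 12 months. At 72 h there were 4 untreated and 4 ATRi mice at each age. The labels give some mice both before and 72 h after PH, among them all 8 of the 12-month mice at 72 h.

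Each table held the authors' log2 level (sigma) for the same 11119 genes. The read depth of the samples is unknown. For 8 groups the tables held 1 mean with no spread between mice, and for the 12-month ATRi livers at 72 h they also held the 4 livers singly (mice M545, M546, M547 and M548). Differences are log2 values, the first-named group minus the second. In 11 comparisons of means no replicate spread exists, so differences are described by size (1 or more) and lists of genes by the percentile of their median among 10000 random lists of matched level (a list stood apart in the lowest or highest 2.5%). In the 5 comparisons with the 4 single livers, limma gave a test. The lowest level in the tables was between 0.049 and 0.548, which bounds the differences of genes near it.

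**Figure D1:**
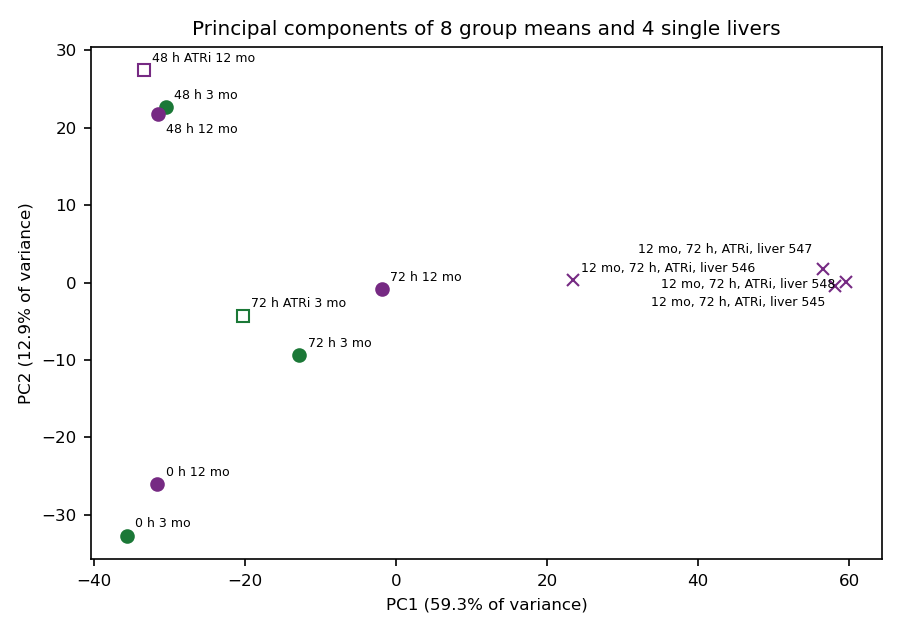
Principal components of the 8 group means and 4 single livers (axes: component scores, with the percent of variance). Component 1 carried 59.3% of the variance and placed livers M545, M547 and M548 at 56.5 to 59.6, liver M546 at 23.4 and the untreated 12-month mean at 72 h at −1.9.

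The first comparison asked how livers differed with age before surgery. Genes of fatty acid oxidation and PPARα targets were lower at 12 than at 3 months, with all 23 measured members below 0 and 8 lower by 1 or more. The largest differences were in the ω-hydroxylases Cyp4a14 (−5.02, mean level 3.47 against 8.49), Cyp4a10 (−4.42) and Cyp4a31 (−3.06) and in the thioesterase Acot3 (−2.27). Acute phase genes, whose products the liver secretes in inflammation, were higher at 12 months in 23 of 25 members and by 1 or more in 10, among them Orm3 (3.76), Saa1 (2.57) and the metallothionein Mt1 (2.40). Of 17 measured genes of inflammation and chemokines, 14 were higher, 9 of them by 1 or more, with Cxcl14 at 2.89, Tnfaip3 at 1.91, Ccl2 at 1.77 and Il1b at 1.71. Tifa, an adaptor upstream of NF-κB, was higher by 3.44 and Tlr2, a receptor for bacterial lipoproteins, by 2.17.

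Markers of immune cells moved with these groups. All 13 markers of Kupffer cells and macrophages were higher at 12 months (median 0.58, Marco 2.01, Lyz2 1.36), as were 9 of 10 neutrophil markers (median 1.03), among them the granule genes Mpo (3.62) and Ngp (3.03), which at 3 months lay close to the lowest value of the tables (0.47 and 0.46). Markers of stellate cells and fibroblasts were lower (median −0.23, 3 of 16 higher). Genes of bile acid synthesis and transport (median −0.34, 4 of 16 higher) and periportal genes (−0.23, 2 of 21) were lower. Cholesterol synthesis (0.22, 18 of 22 higher) and fatty acid synthesis (0.10, 12 of 20) were higher, with Fdps at 1.02, Pnpla3 at 1.81 and Fasn at 1.29. Each of these lists stood apart from random lists. The DNA replication list was higher (0.15, 25 of 33) and stood apart, with no member differing by 1 or more, while the mitosis list did not (−0.01, percentile 91.8) and Mki67, a marker of cycling cells, differed by −0.11. Genes of the integrated and ER stress response were higher (0.41, Creld2 1.47), as were markers of erythroid cells (0.37). Of the female-biased liver genes Fmo2 was lower (−1.32), but several others lay near the lowest values, so the median of this list is not read. In all, 97 genes were higher and 44 lower by 1 or more, without a test on replicates, but 271 and 266 passed by limma with a spread borrowed from the 4 ATRi livers. Cyp4a14 lies on chromosome 4 from 115486200 to 115496142 and Orm3 on chromosome 4 from 63356162 to 63359511 (GRCm38, GENCODE M21).

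The next comparisons followed regeneration in 3-month mice. At 48 h all 30 measured mitosis genes were higher than at 0 h by 1 or more, with a median of 3.05. They included cyclin B2 (Ccnb2, 5.60), its partner kinase Cdk1 (4.67), Birc5 (4.55), Aurka (4.37), Plk1 (4.29) and Mki67 (4.2). Of 33 genes of DNA replication and nucleotide supply, 32 were higher and 22 by 1 or more (median 1.52), among them Rrm2 of ribonucleotide reductase (3.03) and the helicase subunits Mcm5 (2.94) and Mcm6 (2.75). In the list of ATR, checkpoint and fork repair genes, 33 of 38 were higher (median 0.66), with Clspn at 1.80 and Chek1 at 1.64, whereas Atr itself differed by 0.17. G1/S regulators had a median of 0.50 (13 of 17 higher), with Foxm1 at 3.34, Ccne1 at 2.72 and Ccnd1 at 1.56, and E2f8 at −2.23.

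Of the p53 targets, 23 of 30 were higher at 48 h (median 0.48), among them Phlda3 (4.10), Gtse1 (3.72) and the cell cycle inhibitor Cdkn1a (2.39). Acute phase genes were higher in 22 of 25 (median 0.94), with Mt1 at 4.34, Steap4 at 3.21 and Saa1 at 2.88. Hepatocyte functions moved the other way. Genes of fatty acid oxidation (median −0.75, 10 of 23 lower by 1 or more), bile acid synthesis and transport (−0.69, 4 of 16), cholesterol synthesis (−0.44) and periportal genes (−0.57) were lower. Cyp4a10 differed by −3.48, Cyp4a14 by −2.92 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by −1.36, while Tat, a periportal aminotransferase, was higher by 3.63. Male-biased liver genes, many set by the pulses of growth hormone, were lower in 15 of 16 (median −1.06, Hsd3b5 −2.56). Markers of sinusoidal endothelial cells (−0.61), T and NK cells (−0.48) and B and plasma cells (−0.53) were lower, and those of stellate cells and fibroblasts higher (0.24, Col1a1 1.42). All lists in this paragraph stood apart from random lists. Genes of ribosome biogenesis (0.07), secreted hepatocyte proteins (−0.02), circadian clock outputs (−0.19) and pericentral genes (−0.10) did not. Of the replication-dependent histones 2 of 21 were measured, with Hist1h1b at 1.25. None of the 13 mitochondrially encoded genes was in the tables. The counts were 418 genes higher and 297 lower, but 706 and 767 passed with the borrowed spread.

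At 72 h in 3-month mice the same division genes were still above 0 h, by less. The mitosis median was 1.90, with 28 of 30 genes higher by 1 or more, among them Ccnb2 (4.14), Birc5 (3.26), Cdk1 (3.15) and Mki67 (3.09). DNA replication genes had a median of 0.55 (27 of 33 higher), with Rrm2 at 2.19 and Mcm5 at 1.78, and ATR and fork repair genes 0.12 (23 of 38 higher). Phlda3 was higher by 2.89, Cdkn1a by 1.46 and Mt1 by 3.93. Fatty acid oxidation genes had a median of −0.47 (Cyp4a10 −3.05, Cyp4a32 −2.08) and male-biased genes −0.73 (Hsd3b5 −1.89), both apart from random lists. Bile acid genes (−0.07) and cholesterol synthesis genes (−0.05) did not stand apart. Stellate cell and fibroblast markers were higher in 13 of 16 (0.39, Col3a1 1.02) and senescence-associated genes in 8 of 14 (0.30), and these lists stood apart. The counts were 274 higher and 225 lower, and 339 and 156 when the differences were centred on their median of −0.091. With the borrowed spread, which treats mice shared with the 0 h mean as independent, 512 passed as higher and 1152 as lower.

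Compared with 48 h, 72 h in 3-month mice had lower levels of all 30 mitosis genes (median −1.05, 22 lower by 1 or more) and all 33 replication genes (−0.84, 11 by 1 or more). Cenpa differed by −2.08, Aurka by −1.83, the licensing factor Cdt1 by −1.81 and Mki67 by −1.11. Genes of hepatocyte function were higher: bile acid synthesis and transport (median 0.57, 14 of 16 higher, Cyp7a1 1.80), cholesterol synthesis (0.46, 19 of 22), fatty acid synthesis (0.44, 16 of 20, Acaca 1.32) and periportal genes (0.53, 17 of 21, Ass1 1.78). Endothelial markers were higher in 15 of 16 (0.78, Ehd3 1.30) and interferon response genes in 24 of 32 (0.33, Oasl2 1.14). Acute phase genes were lower (−0.55, Steap4 −1.94), as were immediate early genes (−0.34, Egr1 −1.58). All these lists stood apart. The insulin receptor substrate Irs2 was higher by 2.72 and the growth factor receptor Egfr by 2.13, while Gstp1 (−2.64) and its neighbour Gstp2 (−2.60) were lower in parallel in every table, so their values may not be separate. The counts were 179 higher and 338 lower, and 151 and 472 with the borrowed spread.

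In 12-month mice at 48 h the division genes were about as high above 0 h. All 30 mitosis genes were higher by 1 or more (median 2.98), with Cdk1 at 4.57, Aurka at 4.35, Plk1 at 4.24 and Mki67 at 4.05. The replication list had a median of 1.43 (32 of 33 higher, Rrm2 3.07, Mcm5 3.05) and the ATR and fork repair list 1.08 (36 of 38 higher, 20 by 1 or more), with Exo1 at 1.72, Chek1 at 1.5 and Atr at 0.55. Cdkn1a was higher by 2.5 and cyclin D1 (Ccnd1) by 1.90. Fatty acid oxidation genes were higher in 22 of 23 (median 0.91, 11 by 1 or more), led by Cyp4a14 (5.85, from 3.47 to 9.32), Cyp4a31 (3.68) and Acot1 (3.17). Lipid synthesis was lower: fatty acid synthesis had a median of −0.68 (1 of 20 higher) with the desaturase Scd1 at −4.50, Pnpla3 at −3.16 and Fasn at −2.25, and cholesterol synthesis −0.99 (1 of 22 higher) with Fdps at −2.48. Cyp7a1 differed by −3.66.

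Immune genes were lower at 48 h in these mice. Macrophage markers were lower in all 13 (median −0.89, Lyz2 −1.59, Csf1r −1.37), neutrophil markers in all 10 (−0.59, Mpo −3.63, Ngp −3.14, both near the lowest value at 48 h), and interferon response genes in 23 of 32 (−0.42, Ifit3 −1.41). Inflammation and chemokine genes had a median of −0.40 (Cxcl14 −1.84, Il1b −1.77). The acute phase median was 0.17, with Mt1 at 2.16 but Orm1 and Orm3 both at −2.0. Endothelial (−0.44), T and NK cell (−0.45), B and plasma cell (−0.32) and cholangiocyte (−0.44) markers were lower, those of stellate cells higher (0.24), and all lists of this comparison given here stood apart. The counts were 363 higher and 206 lower, but 606 and 519 passed with the borrowed spread.

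At 72 h in 12-month mice the mitosis genes stayed far above 0 h (median 2.43, 30 of 30 higher by 1 or more; Plk1 4.09, Ccnb2 3.91, Mki67 3.11), while replication genes had a median of 0.63 and ATR and fork repair genes 0.19. Interferon response genes were higher in all 32, and by 1 or more in 24 (median 1.23), with the nucleic acid sensor Zbp1 at 2.81, Rsad2 at 2.30 and Ifi44 at 2.17. Macrophage markers were higher in 11 of 13 (0.54, Marco 2.45, Cd5l 1.58) and neutrophil markers in 8 of 10 (0.76, Ngp 1.71, Mmp9 1.44). Acute phase genes had a median of 0.62 (22 of 25 higher, Mt1 2.14, Il1r1 1.57, Crp 1.42), and p53 targets 0.41 (26 of 30, Phlda3 2.56, Cdkn1a 1.51). Fatty acid synthesis was lower (−0.47, Pnpla3 −2.40, Pklr −1.66), as were male-biased genes (−0.48, Hsd3b5 −2.33, Mup21 −1.80). Immediate early genes were lower (−0.35, Nr4a1 −2.16). All these lists stood apart. The counts were 325 higher and 112 lower, but 500 and 906 passed with the borrowed spread. The 0 h mean includes the mice measured at 72 h, which the borrowed spread treats as independent.

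From 48 to 72 h in 12-month mice, interferon and immune genes were higher and replication genes lower. All 32 interferon response genes were higher (median 1.85, 23 by 1 or more; Ifit3 3.25, Ifi44 3.19, Rsad2 3.09, Zbp1 2.66). So were all 13 macrophage markers (1.49, Marco 2.88, Csf1r 2.30) and 9 of 10 neutrophil markers (1.64, Ngp 4.85, Mpo 3.61, Ltf 2.97, each near the lowest value at 48 h). Lipid synthesis was higher, with cholesterol synthesis at a median of 1.15 (21 of 22 higher, Fdps 2.95) and Scd1 at 3.68, and Cyp7a1 was higher by 3.55. Fatty acid oxidation was lower in 21 of 23 (−0.94, Cyp4a14 −3.16, Pdk4 −2.84, Acot1 −2.60). All 33 replication genes (−0.85, Prim1 −1.43, Rrm2 −1.28) and all 30 mitosis genes (−0.54) were lower, the latter by 1 or more in 1 gene (Spc25 −1.08). All these lists stood apart. The counts were 369 higher and 210 lower, and 467 and 138 when centred on the median difference of −0.097, but 324 and 461 passed with the borrowed spread.

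**Figure D2:**
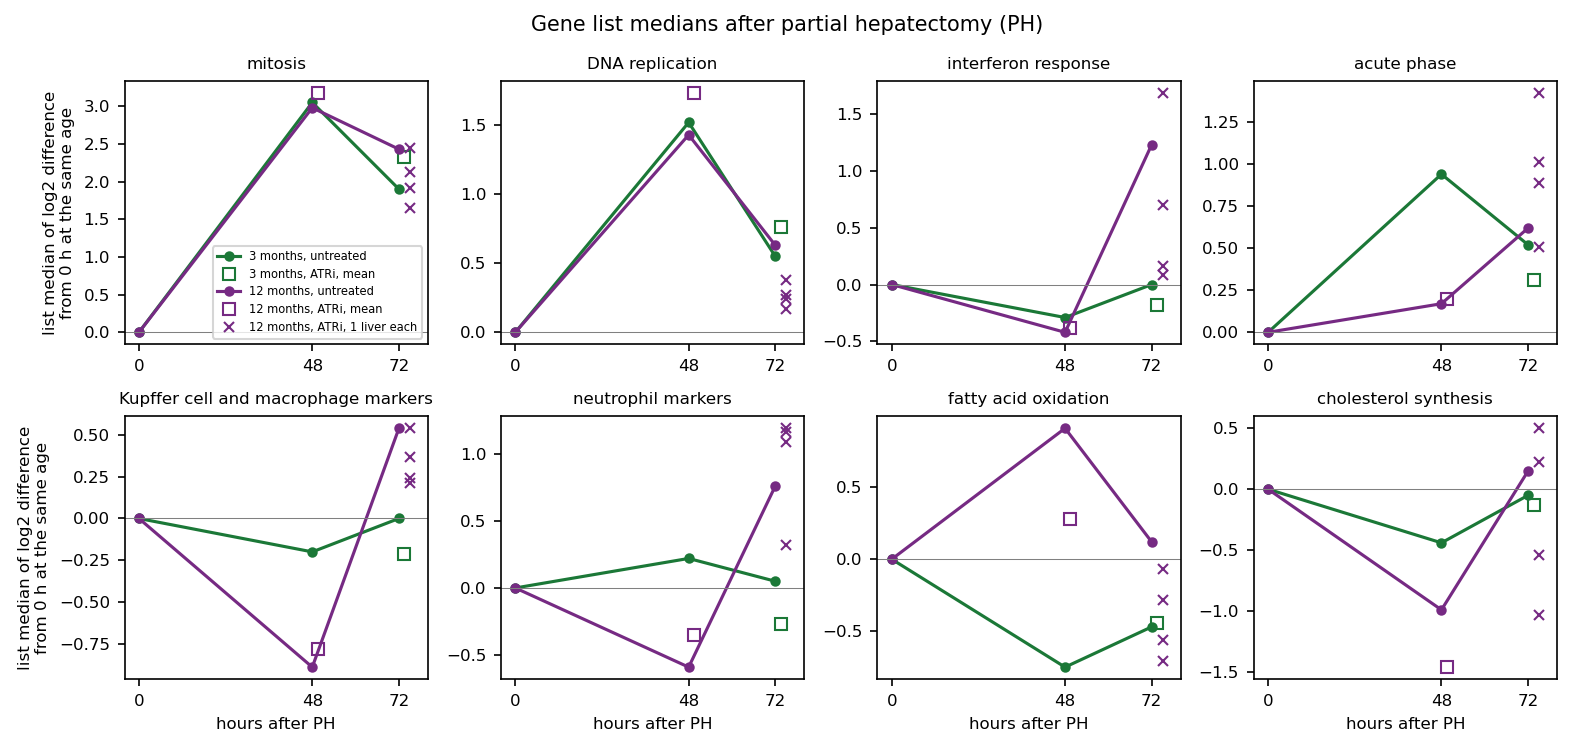
Median log2 difference of 8 gene lists from 0 h at the same age, by hours after PH; lines join untreated means, squares are ATRi means and crosses are the 4 single ATRi livers. The interferon median was 1.23 in untreated 12-month mice at 72 h and 0 in 3-month mice, and the fatty acid oxidation medians at 48 h were 0.91 and −0.75.

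The comparisons of 12 with 3 months after PH asked how age altered regeneration. At 48 h the proliferation lists were close in both ages: the mitosis median was −0.12 (Ccnb2 −1.02, Mki67 −0.25), that of DNA replication 0.19 (28 of 33 higher, none by 1 or more) and that of ATR and fork repair 0.17. The ages differed in lipid metabolism. All 23 fatty acid oxidation genes were higher at 12 months (median 0.97, 11 by 1 or more), among them Cyp4a14 (3.75), the pyruvate dehydrogenase kinase Pdk4 (2.81) and Acot3 (2.12), while fatty acid synthesis genes were lower (−0.21, Scd1 −4.64, Fasn −1.64, Acly −1.58). Cyp7a1 differed by −2.91 and the sterol desaturase Sc5d by −2.0. Pericentral genes were higher (0.27, Cyp2c37 1.87) and periportal genes lower (−0.37, Cps1 −1.34). The p53 targets (−0.21, Bbc3 −0.96), interferon genes (−0.24) and macrophage markers (−0.23, Cd163 −0.93) were lower, and stellate cell genes too (−0.10, Acta2 −1.22, Col1a1 −1.16). All these lists stood apart, and 87 genes were higher and 64 lower by 1 or more, but only 6 and 6 passed with the borrowed spread (963 at an unadjusted p under 0.05).

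**Figure D3:**
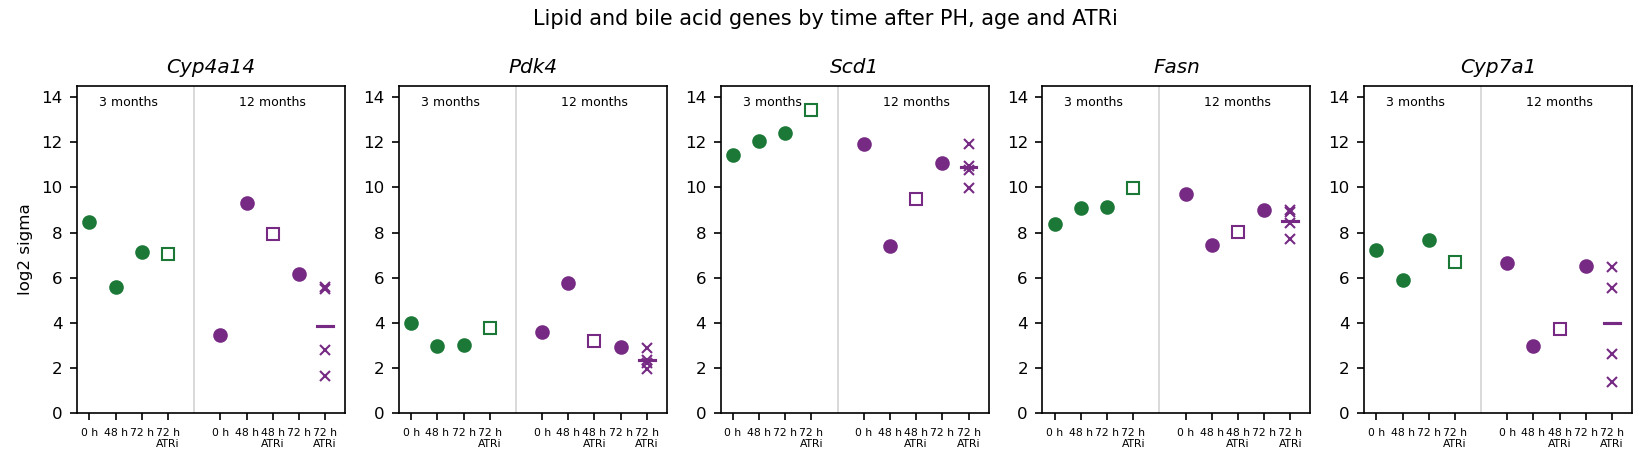
Log2 level of Cyp4a14, Pdk4, Scd1, Fasn and Cyp7a1 in each group (circles untreated, squares ATRi means, crosses single ATRi livers with a bar at their mean). At 12 months Cyp4a14 was 3.47 at 0 h and 9.32 at 48 h, and Scd1 was 11.91 and 7.41.

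At 72 h inflammatory and interferon genes separated the ages. All 32 interferon response genes were higher at 12 months (median 1.18, 19 by 1 or more), with Zbp1 at 2.60, Cmpk2 at 2.32, Ifi44 at 2.20 and Isg15 at 1.96. In the 4 single ATRi livers of 12-month mice at 72 h, this list's median above 0 h ran from 0.08 to 1.68. Mice can thus differ widely in this list, and the 2 means give no spread to set the age difference against. Acute phase genes were higher in 23 of 25 (1.01, Orm1 2.73, Orm3 2.71, Saa2 1.58), and inflammation genes in 15 of 17 (0.32, Cxcl14 2.72, Cxcl13 2.62, Tnfaip3 1.70). Markers of neutrophils were higher in all 10 (1.32, Ngp 4.97, Mpo 3.90, Ltf 3.11, each close to the lowest value at 3 months) and of macrophages in all 13 (0.98, Lyz2 2.04, Marco 1.99), while endothelial markers did not stand apart (−0.06) and stellate markers were lower (−0.33, Acta2 −1.15). Mitosis genes were higher in 28 of 30 (0.50, Cenpa 0.94, Plk1 0.87), none by 1 or more. The ER chaperone genes Creld2 (2.34) and Hyou1 (1.42) were higher and the stress-induced pseudokinase Trib3 (−1.66) lower. Fatty acid synthesis (−0.31, Scd1 −1.32), bile acid genes (−0.34, Cyp7a1 −1.16), pericentral (−0.27) and periportal genes (−0.33, Etnppl −1.70) were lower. Except where said, the lists stood apart, and 219 genes were higher and 86 lower, and 122 and 80 passed with the borrowed spread. Zbp1 lies on chromosome 2 from 173206612 to 173218923.

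ATRi was compared with no treatment at the same age and time to ask what blocking ATR changed during regeneration. At 48 h in 12-month mice few genes differed by 1 or more, 36 higher and 28 lower, and 0 and 2 passed by limma with the borrowed spread (707 at an unadjusted p under 0.05). Fatty acid oxidation genes were lower in 21 of 23 (median −0.62, 7 by 1 or more), with Cyp4a10 at −2.98, Pdk4 at −2.57, Cyp4a32 at −1.92 and Cyp4a14 at −1.38, and Scd1 was higher by 2.06. This list's median level was 6.71 in the untreated mean of 3 mice, 6.0 with ATRi and 5.0 to 5.87 in the other group means. The same untreated mean enters the differences of this list between ages and between times at 12 months, so these are not separate findings. An effect of ATRi cannot be told apart from a high untreated mean. Cholesterol synthesis genes were lower (−0.32, 4 of 22 higher, Cyp51 −1.34, Msmo1 −1.13). Proliferation lists were a little higher, with medians of 0.24 for DNA replication (29 of 33 higher, Cdc6 0.83), 0.25 for mitosis (27 of 30, Bub1b 0.53), 0.21 for ATR and fork repair (30 of 38, Timeless 0.56) and 0.20 for p53 targets (21 of 30, Ak1 1.13, Bbc3 0.99). The chemokines Ccl2 (1.70) and Ccl7 (1.66), which moved in parallel as neighbours, the matrix gene Thbs1 (1.70) and the collagens Col1a1 (1.36) and Col1a2 (1.16) were higher, and the β-globins Hbb-bt (−2.45) and Hbb-bs (−2.44) lower. The β-globins also moved in parallel as neighbours, so their values may not be separate. All lists named here stood apart, without a test on replicates. Variation between mice is not excluded by this. Between the 4 single ATRi livers at 72 h, the SD of list medians was 0.27 for mitosis, 0.19 for p53 targets and 0.7 for cholesterol synthesis. It was 0.11 for DNA replication and 0.09 for ATR and fork repair.

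At 72 h in 3-month mice, 6 genes were higher and 14 lower by 1 or more with ATRi, and 0 and 1 passed by limma with the borrowed spread (560 at an unadjusted p under 0.05). Replication (median 0.29, 28 of 33 higher, Rrm2 0.81, Mcm5 0.75), mitosis (0.36, 29 of 30, Ttk 0.68) and ATR and fork repair genes (0.22, 36 of 38, Chek2 0.59) were higher, and Cdkn1a differed by 0.64. Fatty acid synthesis genes were higher (0.11, Scd1 1.02, Fasn 0.84). Immune lists were lower: inflammation and chemokines (−0.22, Cxcl13 −1.28, Il1b −0.91), acute phase (−0.15, Socs3 −1.37), interferon (−0.12, Gbp2 −0.72), macrophage markers (−0.27, Csf1r −0.44) and neutrophil markers (−0.15, Mmp9 −0.75). All these lists stood apart. Bhmt, a methyltransferase of methionine metabolism, was higher by 1.17 and Hbegf, a ligand of EGFR, by 1.10, and Tifa (−1.40), Asns (−1.31) and Cyp7a1 (−0.98) were lower.

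At 72 h in 12-month mice the ATRi livers differed from untreated ones more widely, and this comparison has a test. Among the genes past it, Tnfaip3, an inhibitor of NF-κB signalling, rose by 3.11 ± 0.42 (SE, 4 livers), Btg3 by 3.02 ± 0.43, Irs2 by 2.92 ± 0.49, the interleukin 1 receptor Il1r1 by 2.51, the acute phase protein Crp by 2.27 ± 0.20, Tat by 1.89 and the p53 target Trp53inp1 by 1.72, each higher in 4 of 4 livers. Cxcl13 fell by 2.97 ± 0.33, Cyp2a5 by 2.68 (at the lowest value in liver M548, which bounds its size and error), the galectin Lgals4 by 2.07 ± 0.25 and Cyp4a31 by 1.72 ± 0.27, in 4 of 4 livers. All 4 livers are set against the same untreated mean and these genes were picked as past the test, so the 4 of 4 adds no support. Adjusted p was 0.0444 for Tnfaip3, Btg3, Cxcl13 and Cyp2a5. Tnfaip3 lies on chromosome 10 from 19000910 to 19015657 and Cxcl13 on chromosome 5 from 95956951 to 95961068.

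By list, DNA replication and nucleotide supply was lower in 29 of 33 members (median −0.48), and 5 members fell and none rose (9 past the threshold adjusted over the list alone), among them Rfc3 (−1.18), Cdt1 (−1.01), Pola2 (−0.95) and Pcna (−0.79 ± 0.15). The list's adjusted p was 1.04e-05, and 0.0123 with an estimated correlation. Cyclin D1 (Ccnd1) fell by 0.72 ± 0.16. Mitosis genes were lower in 29 of 30 (median −0.41), with 2 members falling (Cdca8 −1.02, Ttk −0.80; 2 adjusted over the list alone), adjusted p = 0.000511 but adjusted p = 0.706 with an estimated correlation, and Mki67 differed by 0.19 ± 0.19 (adjusted p = 0.507). In the ATR and fork repair list (median −0.26) 2 members fell, Rad1 (−1.40) and Rpa2 (−1.25), 0 of the list by limma when adjusted over the list alone, and adjusted p = 0.00303 became adjusted p = 0.522 with an estimated correlation. Atr differed by −0.35 ± 0.17 (adjusted p = 0.181). The deposited mean of the ATRi group lay above the mean of its 4 livers by an amount that varied with level. The median offset was 0.144 at mean levels above 2 and up to 3, and 0.212 above 3 and up to 4. If the untreated mean carries a like offset, part of the fall of lists at such levels comes from it, which was not tested.

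Fatty acid oxidation genes were lower in 20 of 23 (median −0.67), 4 fell, Cyp4a31 and Cyp4a32 (−1.49) among them, and 5 passed adjusted over the list alone; the list's adjusted p was 1.92e-06, and 0.0211 with an estimated correlation. Interferon genes had a median of −0.58 (2 of 32 higher, Cmpk2 −1.37, Rsad2 −1.36) with 0 genes past limma's threshold and 5 at an unadjusted p under 0.05; liver M547 was higher than the untreated mean (median 0.43) and the others lower (−0.90 without M547). The list's adjusted p of 0.0054 became adjusted p = 0.706 with an estimated correlation. Macrophage markers were lower (median −0.28, 2 fell: Timd4 −0.89, Ms4a7 −0.67, near the lowest value in livers M545 and M547), adjusted p = 0.00817 but adjusted p = 0.61 with an estimated correlation. Acute phase genes were higher in 17 of 25 (median 0.35, 3 rose) and inflammation genes in 11 of 17 (0.65; 2 rose, 1 fell), with adjusted p = 0.0663 and 0.156, and their medians were 0.13 without liver M548 and 0.40 without liver M545. Neutrophil markers were higher in 8 of 10 (0.47, adjusted p = 0.485; −0.19 in liver M545 and 0.49 to 0.6 in the others), with 0 past limma's threshold and 2 at an unadjusted p under 0.05. Cyp7a1 was lower by a wide spread (−2.52 ± 1.14, adjusted p = 0.155), with levels of 1.38 in liver M545, 2.63 in M548, 5.53 in M547 and 6.46 in M546. Pericentral genes were lower (−0.66, 6 of 24 higher, Tbx3 −1.56) with adjusted p = 0.0165, but adjusted p = 0.61 with an estimated correlation, and male-biased genes (−0.77, 3 fell) with adjusted p = 0.0113, but adjusted p = 0.61 with an estimated correlation. Liver M545 weighed most in both lists, whose medians without it were −0.30 and −0.41. Of 4 measured sex chromosome genes, Uty rose by 1.30 and Ddx3y by 0.74.

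In all, 689 genes rose and 352 fell at adjusted p under 0.05 (limma), 4151 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0301. Among the 9000 genes with the highest mean, 126 rose and 147 fell. The lowest level was 0.049 in the untreated mean and 0.272 to 0.548 in the 4 livers, so genes near it can appear to rise. The excess of rising genes therefore cannot be read as an effect of ATRi. No gene rose after quantile normalization (3625 at an unadjusted p under 0.05), when each mean weighed as 1 library, or without liver M545, M547 or M548, and 2300 rose and 1028 fell without liver M546. By size, 840 genes were higher and 93 lower by the authors' mean, 577 and 231 by the mean of the 4 livers, and 577 and 230 after quantile normalization. The deposited mean lay above the mean of the 4 livers by a median of 0.088. In all 5 tested comparisons the differences followed intron length across genes, which are not independent replicates (Spearman's rho 0.43 here, 0.31 for age under ATRi, 0.41 for 72 against 48 h, and 0.40 for 72 h against 0 h and for the ATRi effect between ages), and in the other 11 rho lay between −0.17 and 0.28. Liver M546 alone had 115 genes higher and 116 lower by 1 or more than the untreated mean, and livers M545, M547 and M548 had 812 to 995 higher.

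**Figure D4:**
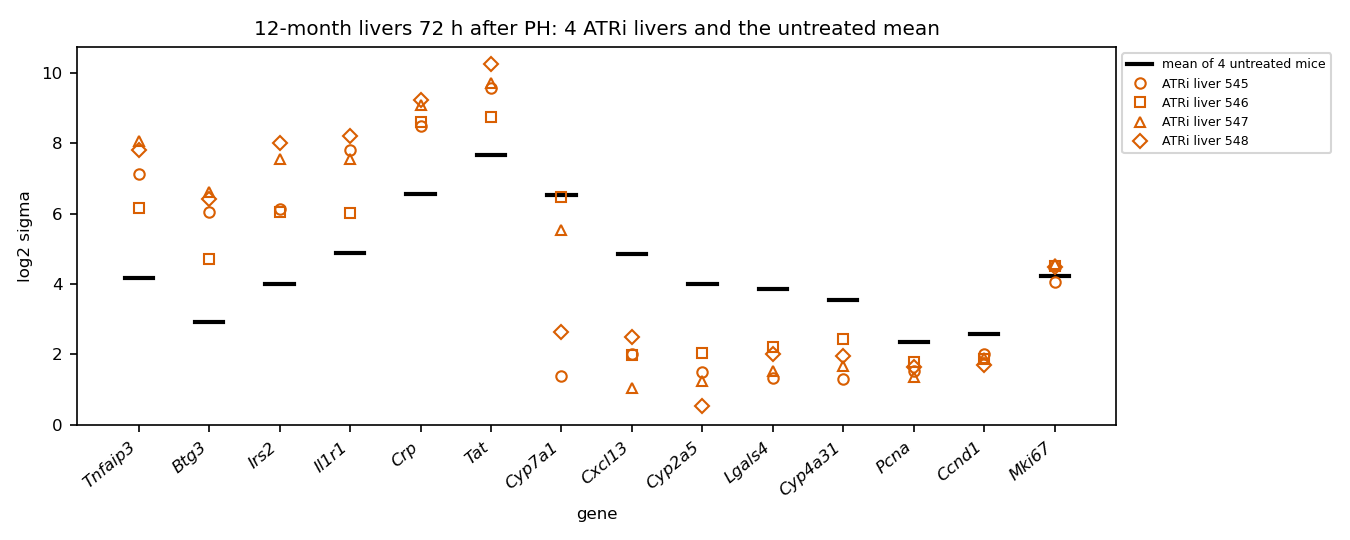
Log2 level of 14 genes in the 4 ATRi livers of 12-month mice at 72 h (symbols) and the mean of 4 untreated mice of that age (bars). Tnfaip3 rose by 3.11 and Cxcl13 fell by 2.97, while the ATRi livers spread widely in Cyp7a1 (SE 1.14) and Mki67 differed by 0.19.

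The difference between the ATRi effect at 12 and at 3 months was itself tested at 72 h. The list with the lowest adjusted p was DNA replication and nucleotide supply, whose median was −0.75, with 29 of 33 members lower, among them Rfc3 (−1.72), Cdt1 (−1.38), Orc6 (−1.34) and Rrm2 (−1.20 ± 0.39). No member passed over all genes (limma; 23 at an unadjusted p under 0.05), 15 passed adjusted over the list alone, and the list's adjusted p was 1.45e-09, and 8.55e-05 with an estimated correlation. An offset of the untreated 12-month mean, as described for ATRi at 12 months, could be part of this difference too, which was not tested. Mitosis genes had a median of −0.78 (0 of 30 higher; Ttk −1.48, Cdca8 −1.42; 6 adjusted over the list alone; adjusted p = 1.46e-08, but adjusted p = 0.537 with an estimated correlation). ATR and fork repair genes had a median of −0.46 (5 of 38 higher; adjusted p = 1.21e-06, but adjusted p = 0.113 with an estimated correlation) and fatty acid oxidation genes −0.59 (adjusted p = 9.37e-05, but adjusted p = 0.099 with an estimated correlation). Inflammation genes had a median of 1.34 (11 of 17 higher, Tnfaip3 3.25, Relb 2.22; 6 adjusted over the list alone) with adjusted p = 0.0342, but adjusted p = 0.691 with an estimated correlation, and their median was 0.87 without liver M545.

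Of single genes, 1 passed limma's threshold (2749 had an unadjusted p under 0.05), and it cannot be read as a difference between ages. This gene, Cyp2a4, was at the lowest value of the untreated 12-month table (0.049) and at 0.5 to 0.7 in the 4 livers, whose own lowest values were 0.272 to 0.548. Its computed difference of 2.12 rests on single 3-month means of 1.82 untreated and 0.21 with ATRi, and its SE carries no spread of expressed levels. It did not pass with the 9000 genes of highest mean, after quantile normalization, without the trend, or without liver M545 or M548, and without liver M546 there were 1182 genes higher and 397 lower. By size, 1020 genes were higher and 221 lower, 783 and 372 by the mean of the 4 livers, and 721 and 411 after quantile normalization.

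Under ATRi at 72 h, 12-month livers were compared with the 3-month mean. Neutrophil markers rose in 9 of 10 members (median 2.57; Ngp 5.03 ± 0.53, near the lowest value at 3 months, Mmp9 3.01; 10 adjusted over the list alone; adjusted p = 2.31e-07, and 0.0016 with an estimated correlation). Acute phase genes rose in 20 of 25 (median 1.35; Crp 4.18 ± 0.20, Il1r1 3.80, Il1rn 3.48; 23 adjusted over the list alone; adjusted p = 3.33e-16, and 0.0196 with an estimated correlation). Tnfaip3 rose by 4.94 ± 0.42, Tifa by 4.90 ± 0.27 and Cxcl14 by 4.06. Macrophage markers rose in 8 of 13 (1.11, Lyz2 1.93; adjusted p = 5.91e-07, but adjusted p = 0.0798 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 23 and rose in 1 (−0.81, Cyp4a14 −3.20, Cyp4a10 −2.57, at the lowest value in 2 livers; adjusted p = 2.31e-07, and 0.00969 with an estimated correlation), replication genes in 16 of 33, with 1 rising (−0.66, Rrm2 −1.35, Pcna −0.80; adjusted p = 6.36e-05, and 0.0142 with an estimated correlation) and stellate cell markers in 7 of 16 (−0.43, Col1a2 −1.11; adjusted p = 0.00558, and 0.00969 with an estimated correlation). For stellate cell markers the estimated correlation was below 0 and set to 0, so their second test is no stricter than the first. Atr fell by 0.94 ± 0.17 (adjusted p = 0.013).

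In this comparison 1948 genes rose and 1494 fell, but 4 and 4 when each mean weighed as 1 library, 839 and 517 without liver M547 and 889 and 583 without liver M548. Among the 9000 genes with the highest mean, 1266 rose and 1453 fell. By size 1183 were higher and 267 lower, 931 and 439 by the mean of the 4 livers and 898 and 491 after quantile normalization.

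From 48 to 72 h under ATRi at 12 months, replication genes fell in 30 of 33 (median −1.61; Orc6 −2.52, Cdt1 −2.46, Mcm5 −1.67 ± 0.22; adjusted p = 2.23e-21, and 7.14e-11 with an estimated correlation), ATR and fork repair genes in 31 of 38 (−1.05; Rpa2 −2.63, Rad1 −2.30, Chek1 −0.98; adjusted p = 5.66e-15, and 0.00136 with an estimated correlation) and G1/S regulators in 10 of 17, with 2 rising (−0.91; E2f1 −2.04, Ccnd1 −1.87; adjusted p = 0.00139, and 0.00136 with an estimated correlation). Mitosis genes fell in 27 of 30 (−1.11; Aurka −1.76, Mki67 −0.92 ± 0.21; adjusted p = 6.42e-09, but adjusted p = 0.346 with an estimated correlation). Egfr rose by 5.25 ± 0.30, Pid1 by 5.25 ± 0.45, Crp by 4.44 ± 0.22 and the elongase Elovl6 by 3.48, and fatty acid synthesis genes rose in 8 of 20 (0.65; adjusted p = 0.00057, and 0.000541 with an estimated correlation). For G1/S regulators and fatty acid synthesis the estimated correlation was below 0 and set to 0, so their second test is no stricter than the first. Markers of neutrophils rose in 8 of 10 (2.16; adjusted p = 6.66e-05, and 0.011 with an estimated correlation) and markers of macrophages in 9 of 13, with 1 falling (1.08; adjusted p = 3.03e-05, but adjusted p = 0.168 with an estimated correlation). Acot1 fell by 3.92 ± 0.38 and Cyp4a14 by 4.08 ± 1.02. In all 1974 genes rose and 2350 fell, 343 and 540 when each mean weighed as 1 library, 1278 and 1420 without liver M547, and 1557 fell without liver M548. By size 1412 were higher and 779 lower, and 1148 and 1050 by the mean of the 4 livers.

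Against 0 h at 12 months, whose mean includes the same 4 mice, the ATRi livers at 72 h still had all 30 mitosis genes raised (median 1.96; Ccnb2 3.68, Cdk1 3.39, Mki67 3.29 ± 0.17; 30 adjusted over the list alone; adjusted p = 1.74e-31, and 0.024 with an estimated correlation). Of p53 targets 15 of 30 rose and 2 fell (0.51; Phlda3 2.62, Trp53inp1 2.42, Cdkn1a 1.88 ± 0.31; adjusted p = 0.000417, and 0.00622 with an estimated correlation). Acute phase genes rose in 17 of 25 (0.92; Il1r1 4.08, Crp 3.69; adjusted p = 5.25e-08, but adjusted p = 0.426 with an estimated correlation). In the replication list 13 of 33 rose and 6 fell (0.33; Mcm5 1.70, Mcm10 −1.54; adjusted p = 0.271). Male-biased genes fell in 7 of 16 (−0.83; Mup21 −3.80, Hsd3b5 −3.67, bounded by the lowest value, at which it lay in liver M545 and near it in M547; adjusted p = 0.00437, but adjusted p = 0.588 with an estimated correlation), with a median of −0.38 without liver M545. Egfr rose by 4.64 ± 0.24. In all 2568 genes rose and 2822 fell, but 196 and 172 when each mean weighed as 1 library. By size 1452 were higher and 566 lower, 1186 and 847 by the mean of the 4 livers and 1156 and 876 after quantile normalization.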

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

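No test in this part was chosen after its result was seen. The ATRi effect at 72 h was tested for a difference between ages, with the spread of the 4 livers of 12-month mice alone. By cameraPR, which sets a list's statistics against those of all other genes, 7 lists passed, and by limma 1 gene. Adjusted p-values of lists are given first for a preset and then for an estimated correlation. With the latter only the replication list and the female-biased list passed. The sign was the same in 4 of 4 livers for each of these lists, but also in 12 of all 30 lists, since every liver is set against the same 3 means. DNA replication and nucleotide supply had a median of −0.75, with adjusted p = 1.45e-09 and adjusted p = 8.55e-05 with an estimated correlation. Its median level was 3.05 in the untreated 12-month mean. The deposited ATRi mean lay above its livers by a median of 0.144 at levels above 2 and up to 3, and 0.212 above 3 and up to 4. A like offset in the untreated 12-month mean would be part of this difference, which was not tested. Differences between ages also followed intron length (Spearman's rho 0.4). The mitosis list had a median of −0.78, with adjusted p = 1.46e-08 but adjusted p = 0.537 with an estimated correlation. ATR, checkpoint and fork repair genes had a median of −0.46, with adjusted p = 1.21e-06 but adjusted p = 0.113 with an estimated correlation. For fatty acid oxidation and PPARα targets it was −0.59, with adjusted p = 9.37e-05 but adjusted p = 0.099 with an estimated correlation. Female-biased liver genes had a median of 0.36, with adjusted p = 0.00141 and adjusted p = 0.0344 with an estimated correlation, but their median level (0.6 in the untreated 12-month mean, 0.7 to 0.93 in the livers) was close to the lowest values of these tables (0.049, and 0.272 to 0.548), which differ, so this call cannot be read as a difference between ages. For acute phase genes it was 0.25, with adjusted p = 0.0126 but adjusted p = 0.75 with an estimated correlation, and the median was 0.07 without liver M548. For inflammation and chemokines it was 1.34, with adjusted p = 0.0342 but adjusted p = 0.691 with an estimated correlation, and the median was 0.87 without liver M545. The gene was Cyp2a4 (computed difference 2.12, adjusted p = 0.0105), but its levels of 0.5 to 0.7 in the 4 livers and 0.049 in the untreated 12-month mean are at or near the lowest of their tables, so neither its error nor its sign in the 4 livers is evidence, and it did not pass without liver M545 or M548.

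Among the 4 ATRi livers of 12-month mice at 72 h, 5 of 94 groups of 4 values had 1 liver far from the others by Dixon's ratio (the gap to the nearest liver over the whole range), and chance gives about 1 in 20. The median level of male-biased liver genes was 1.15 in liver M545 and 2.84 to 3.05 in the others (ratio 0.889). Cholangiocyte markers had a median level of 1.67 in liver M545 and 0.84 to 0.96 in the others (0.853). Mcm10, a factor that activates the replicative helicase, was at 2.14 in liver M545 and 3.29 to 3.33 in the others (0.962). The neutrophil granule gene Ngp was at 6.8 in liver M546 and 4.47 to 4.85 in the others (0.837). Slc4a1, the anion exchanger of red cells, was at 2.73 in liver M546 and 0.98 to 1.13 in the others (0.913).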

How the results depend on the processing

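Removal of the trend on intron length and the deposited mean as limma's level were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the tables give levels of single mice in only 1 group. The depth of the samples is unknown, and genes near the lowest level of a table have bounded differences. The filter to 12000 genes removed nothing, so lifting it tests nothing. With the spread borrowed from the 4 livers, the 11 comparisons of means gave 0 to 706 genes higher and 1 to 1152 lower by limma (the 0 with 707 and 560 genes at an unadjusted p under 0.05, ATRi at 48 h in 12-month and at 72 h in 3-month mice). Between times, the balance turned from more genes higher by size to more lower past this test for 48 and 72 h against 0 h at 3 months and for 72 h against 0 and 48 h at 12 months. Against the counts by size, 97 and 44 became 271 and 266 for age before PH, 363 and 206 became 606 and 519 for 48 h against 0 h at 12 months, 87 and 64 became 6 and 6 for age at 48 h (963 at an unadjusted p under 0.05), and 219 became 122 for age at 72 h. Causes were not tested unless said. Apart from the borrowed spread and the values below, counts of genes stayed within 1.5 times the reported ones.

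Centred on the median difference, 138 genes were lower at 72 than at 48 h at 12 months, and 146 with ATRi at 72 h at 12 months. After quantile normalization the lower counts were 230 for ATRi at 72 h at 12 months, 491 for age under ATRi, 876 for ATRi at 72 h against 0 h and 411 for the ATRi effect between ages; in the mean of the 4 livers they were 231, 439 (age under ATRi) and 372 (between ages). With the trend on intron length removed, the higher counts were 529 for ATRi at 72 h at 12 months, 965 for ATRi at 72 h against 0 h and 673 for the ATRi effect between ages. Without 1 liver, 194 (M545) to 349 (M546) genes were lower with ATRi at 72 h at 12 months.

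Past limma's test, ATRi at 72 h at 12 months gave 126 genes higher and 147 lower among the 9000 genes with the highest mean, 1050 higher with the deposited mean as level, and 0 and 0 after quantile normalization (3625 at an unadjusted p under 0.05), without trend and robust fit (3957), and with each mean weighing as 1 library (1496), which widens the error by construction. Leaving out 1 liver gave 0 to 2300 higher and 0 to 1028 lower: 0 and 0 without M545 (3489 at an unadjusted p under 0.05) and without M547 (3002), 0 and 1 without M548 (3070), and the highest without M546. For age under ATRi there were 1266 higher among 9000 genes, 4 and 4 with a mean as 1 library, and 839 to 2673 higher and 517 to 1856 lower without 1 liver, lowest without M547 and 889 and 583 without M548. From 48 to 72 h under ATRi there were 343 and 540 with a mean as 1 library, and 1278 to 2422 higher and 1420 to 2558 lower without 1 liver, lowest without M547 (1557 lower without M548). ATRi at 72 h against 0 h gave 196 and 172 with a mean as 1 library. The ATRi effect between ages gave 0 genes higher among 9000 genes (2032 at an unadjusted p under 0.05), after quantile normalization (2491), without trend and robust fit (2666) and with a mean as 1 library (425), and 0 to 1182 higher and 0 to 397 lower without 1 liver: 0 without M545 or M548, 1 higher without M547, and the highest without M546.

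List medians moved by less than the SD of the 4 livers' medians in 396 of 480 cases among 9000 genes, 446 after quantile normalization, 459 when centred and 423 without the trend on intron length. A change of sign was counted apart only for lists that stood apart from random lists, so other lists may have changed sign within these counts. Several changed sign. With the trend removed, inflammation at 48 h against 0 h at 3 months went from 0.57 to −0.05, T and NK cell markers with ATRi at 72 h at 12 months from −0.03 to 0.16 (0.03 without M545) and B and plasma cell markers in the ATRi effect between ages from −0.17 to 0.05. Among 9000 genes, erythroid markers at 48 h against 0 h at 12 months went from −0.30 to 0.03 and cholesterol synthesis at 48 h between ages from −0.13 to 0.04. Cholesterol synthesis for age under ATRi (0.14) ran from −0.12 to 0.51 without 1 liver (−0.12 without M545, −0.05 without M546), and secreted proteins for ATRi at 72 h against 0 h went from 0.15 to −0.01 after quantile normalization. With an estimated correlation, 28 list tests lost their call and 122 did not change. With the deposited mean in place of the 4 livers, 30 list medians and 17 named differences moved by more than the spread, and 120 and 70 did not. Of 333 named differences, 4 moved after quantile normalization and none when centred. Without the trend on intron length 20 moved and 307 did not.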

Other observations

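Of the tests in this part, the one of the scaling of the tables on the interferon genes was planned before its result was seen; those of intron length, scaling of the deposited mean, macrophages, a single liver, share of hepatocytes, more macrophages and neutrophils, time of day and feeding were chosen after. Several groups of genes not described above also differed between means. At 48 h, 4 of 18 clock genes were lower by 1 or more at 12 than at 3 months, the repressors Nr1d1 (−1.19), Per3 (−1.14) and Per2 (−1.1) and the clock output factor Tef (−1.13), while the list's median of −0.04 did not stand apart; before PH Tef (−1.01) was the member that differed by 1 or more. At 72 h the clock list stood apart (median −0.33, 5 of 18 higher), with the phosphatidate phosphatase Lpin1 at −1.5. From 48 to 72 h at 12 months, genes of ribosome biogenesis were lower in 15 of 16 (median −0.39; Pes1 −0.75, Nolc1 −0.7), and ER stress genes had a median of 0.59 with the chaperone genes Pdia4 (0.97) and Creld2 (0.85) higher and Trib3 (−1.59) lower. The median of the female-biased liver genes is not read, as several lay near the lowest values, which differ between tables. Of those further above them, Fmo2 was lower at 48 h than at 0 h in 3-month mice (−1.74), and Abcd2 (1.64) and the steroid hydroxylase Cyp17a1 (1.18) were higher at 72 than at 48 h. With ATRi at 48 h at 12 months Acot3 (−0.89) and Cyp17a1 (−0.54) were lower, while senescence-associated genes were higher in 11 of 14 (0.3; Gpnmb 0.66, the cell cycle inhibitor Cdkn2b 0.43). The topoisomerase Top2a was higher by 3.63 at 48 h against 0 h at 3 months and by 3.8 at 12 months, and albumin (Alb) at 72 h by 1.07 and 0.78. Under ATRi at 12 months, 4 of 6 erythroid genes rose from 48 to 72 h (median 0.97; Hbb-bt 1.44, Hbb-bs 1.43 and Slc4a1 1.21, near the lowest value at 48 h and 0.79 without liver M546; 6 adjusted over the list alone), with adjusted p = 0.047 but adjusted p = 0.458 with an estimated correlation (limma, cameraPR). Hbb-bt and Hbb-bs ran in parallel as neighbours (SD of their difference 0.01), so they may not be separate members in these counts and tests.

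The 4 ATRi livers of 12-month mice at 72 h were not alike. Against the untreated mean, replication genes had medians of −0.64 to −0.39 and fatty acid oxidation genes of −0.97 to −0.29 in the 4 livers. Liver M545 had pericentral genes at −1.53, endothelial markers at −0.83 and ER stress genes at −1.16, where the other livers lay between −0.31 and −0.22, between −0.14 and 0.04 and between −0.64 and 0.28. Interferon genes were at 0.43 in liver M547 and at −1.22, −0.56 and −1.05 in livers M545, M546 and M548. Cholesterol synthesis genes ran from −1.2 in liver M548 and −0.58 in liver M547 to 0.08 in liver M546 and 0.36 in liver M545, and inflammation genes from −0.05 in liver M546 to 1.0 in liver M547.

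The 840 genes higher by 1 or more with ATRi at 72 h at 12 months went with intron length (Spearman's rho 0.43 across 10239 genes, which are not independent), yet 59.7% of those with a length (808 of 840) stayed higher by 1 or more once that trend was removed. After quantile normalization 68.7% stayed, so scaling does not account for the size of all these differences. No gene passed limma after it, however (3625 at an unadjusted p under 0.05). With 1 liver left out the count in the mean of the livers stayed at 86.0% or more of 577 (from 496 without M548 to 828 without M546). This argues against a single liver as the whole cause of that count, but cannot show a fault shared by livers M545, M547 and M548. Macrophage markers had a mean of the livers' medians of −0.3 (SD 0.2, n = 4), against more macrophages, by a bound rewritten after the values were seen. More neutrophils stay open, since their markers had a mean of 0.36 (SD 0.37) and moved up in livers M546, M547 and M548. The livers do not decide. Liver M545 had 995 genes higher by 1 or more with a neutrophil median of −0.19, and liver M546 115 genes with 0.49, which goes against this explanation. Livers M547 (812 genes, 0.6) and M548 (941 genes, 0.53) go with it. Intron length may still account for part of the pattern, as more unspliced RNA or a difference in RNA quality in livers M545, M547 and M548 would give, which the tables do not show, and scaling for another part. An effect of ATRi in older livers also stays open: limma tested the difference, but with the spread of the treated livers alone, and not what caused it.

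The higher interferon genes at 12 than at 3 months at 72 h had a median of 1.19 after quantile normalization, which argues against scaling of the tables. Macrophage markers exceeded endothelial markers by 1.04, whereas a lower share of hepatocytes would raise both alike. Macrophage markers were higher by 0.98, as a larger number of macrophages and neutrophils would give, so such cells are a candidate explanation, though some interferon genes are also induced in hepatocytes. Before PH, macrophage (3.81 against 2.71) and neutrophil markers (1.99 against 0.52) also had higher median levels at 12 months. Interferon genes did not (3.46 against 3.71), so the markers and these genes did not go together there. Among the ATRi livers, M547 had the highest interferon median (0.43), the lowest for macrophages (−0.47) and the highest for neutrophils (0.6). Liver M545 had the lowest for interferon (−1.22) and for neutrophils (−0.19). These livers thus do not decide. A response of hepatocytes to age stays open and was not tested. Variation between mice stays open as well, since each group has 1 mean. Across the 4 ATRi livers the list's median against the untreated 12-month mean ran from −1.22 to 0.43.

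PPARα targets were lower at 12 than at 3 months before PH and higher at 48 h. Time of day could account for this if clock genes moved in both comparisons, but 1 of 18 differed by 1 or more before PH and 4 at 48 h, so the smaller count of 1 does not decide. Feeding state could move oxidation and synthesis apart, and their list medians were apart by 0.8 or more in both comparisons, but fatty acid synthesis before PH (0.10) was too close to 0 to decide. These 2 explanations cannot be told apart from an effect of age, because hours of sampling and feeding are not given in the sources used here and each group has 1 mean. The untreated 12-month mean at 48 h also enters the lower PPARα targets with ATRi at 48 h, so both explanations stay open there too.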
